A study of Mus musculus with 18 samples.

How the data were processed

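RNA was measured in 18 libraries of dental epithelium from mouse molar tooth germs, 3 per group for wild type and the Hmgn1 and Hmgn2 double knockout at E17, P0 and P5. Per the labels' protocols, dispase at 1 U/ml separated the epithelium from the mesenchyme, 1 µg of total RNA with an integrity number above 7 was depleted of ribosomal RNA, and libraries were made with a NEBNext Ultra II kit. Per the submitters' processing notes, the authors processed the reads with Partek (no version given) on mouse genome build mm10. The aligner, the annotation and the counting of strand are not given in the sources used here. Per the file headers, the library names are those of sorted alignment files with duplicates marked, and whether marked duplicates were left out is not stated. Transcript names are of the Ensembl/GENCODE form at E17 and P0 and RefSeq accessions at P5, so each stage was tested alone.

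The deposited values are RPKM per transcript (scaled by the authors to transcript length and mapped reads). No source states this unit, and whether reads or fragments were counted is unknown. It was read from the values: libraries of the E17 table had a median sum of 479171.6, not the fixed sum of TPM, and for genes with a single transcript 86.1% to 86.9% of low values (E17), 85.9% to 87.9% (P0) and 71.0% to 72.8% (P5) were whole multiples of the value of 1 read, within 0.1. Per the file headers, the deposited number of alignments was 65953495 to 99967427 per library at E17, 74845352 to 108920337 at P0 and 39209676 to 72660832 at P5. The steps of the values give 27.9 to 41.6, 31.3 to 46.4 and 16.8 to 31.0 M mapped reads at E17, P0 and P5, so that 1 read on a transcript of 1 kb is 0.0216 to 0.0594 RPKM. The P0 table has 16384 columns and holds 16381 transcripts of 4841 genes, on chromosomes 1 and 10 and on 11 up to position 96873954, and other genes were not analysed here at P0.

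RPKM of the transcripts of a gene were summed per gene symbol. Older symbols of list members were matched through the RefSeq gene table, and positions were taken from GENCODE M21 on the mm10 assembly. Genes with a value of at least 1 in at least 3 of the 6 libraries of a stage were kept, 13728 at E17, 2062 at P0 and 11423 at P5. Log2(RPKM + 1) was compared between genotypes with limma 3.58.1 (empirical Bayes with trend) in R 4.3.3, two-sided, and genes were called at a Benjamini-Hochberg adjusted p under 0.05. The replicate number was not used as a block. The difference of the genotype effect between stages was the difference of the log2 fold changes over the root of the summed squared standard errors, with Satterthwaite degrees of freedom, adjusted within each pair of stages. Overlaps of calls were tested with Fisher's exact test, two-sided, per direction. The 32 gene lists, fixed before the data were examined like the tests, were tested with camera in limma at a preset correlation of 0.01, adjusted over the lists of a stage with at least 5 genes tested. They cover enamel matrix, ion transport and maturation, dental transcription factors, progenitors, inner enamel epithelium signals, stratum intermedium, keratins and junctions, cornifying epithelium, mesenchyme, odontoblasts and osteoblasts, endothelium, red cells, immune cells, glia and neurons, muscle, salivary gland, cell cycle, HMG proteins and linker histones, histone-modifying enzymes, Hox genes, the Hedgehog, Wnt, BMP and TGF-beta, and FGF pathways, the unfolded protein response, immediate-early genes, mitochondrially encoded genes, abundant non-coding RNA, replication-dependent histones, sex-linked genes, and the neighbours of Hmgn1 and of Hmgn2.

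Genes named in the text follow a rule: Hmgn1 and Hmgn2 in every sample, then at each stage the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose groups do not overlap and whose higher mean is at least 1 RPKM, up to 4 members of each list with the smallest p, and at every stage a fixed set of genes (among them Amelx, Ambn, Enam, Mmp20, Klk4, Amtn, Odam, Sp6, Satb1, Krt14, Shh, Alpl, Col1a1 and Dspp). Predicted, micro-RNA and pseudogene symbols were counted but not named, and a few other genes are not reported here. Other members of lists, and other genes in the differences between stages, were chosen after their values were seen.

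Alternatives were upper-quartile scaling of each library, no filter, a pseudocount of 0.1, limma without trend, an absolute log2 fold change of at least 1 beside the adjusted p, the replicate number as a block, each library left out in turn, an unadjusted p under 0.01 for overlaps, and fry and an estimated correlation for lists. Median-of-ratios scaling, the combinations with upper-quartile scaling, libraries left out with the filter of all 6 kept (for named genes) and the rule of passing in both scalings were added after the data were seen. The fits were tested on simulated data with 200 changed genes per stage, in which genes varied independently and no shift of all genes was put in. At E17 6%, 52%, 100% and 100% of genes changed by 0.25, 0.5, 1 and 2 log2 units were called, at P0 32%, 84%, 98% and 100%, and at P5 14%, 68%, 98% and 100%, with 9 false calls of 138, 3 of 160 and 3 of 143. Of 343 simulated differences between E17 and P5, 233 were called with 17 false calls. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9. The course of wild type across stages was not tested. That test was set for counts on the same gene names at all 3 stages, while the values are RPKM and P5 has another annotation.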

Results

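RNA sequencing measured transcript levels in the dental epithelium of mouse molars from wild-type animals and from animals labelled as double knockouts of Hmgn1 and Hmgn2 (the double knockout), at embryonic day 17 (E17), at postnatal day 0 (P0) and at postnatal day 5 (P5). HMGN1 and HMGN2 are small proteins that bind nucleosomes and loosen compacted chromatin, and the series asks how they take part in the differentiation of ameloblasts, the epithelial cells that deposit enamel. Each of the 6 groups held 3 libraries, 18 in all. The libraries had 65953495 to 99967427 alignments at E17, 74845352 to 108920337 at P0 and 39209676 to 72660832 at P5. Values are RPKM summed over the transcripts of a gene, given as mean ± SD (n = 3 per group throughout). Log2 fold changes (double knockout against wild type) are on the log2(RPKM + 1) scale with their standard error, from limma with Benjamini-Hochberg adjusted p. The P0 values cover chromosomes 1 and 10 and part of 11 only, so Hmgn1, Hmgn2, Shh and Amelx were not analysed here at P0. The labels do not say that the libraries of a group came from separate animals, so the p-values measure the spread between these samples, which may be technical.

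The values of most genes shifted together between genotypes at E17 and at P5, in opposite directions, and little at P0. The median log2 fold change over all genes tested was 0.25 at E17, -0.05 at P0 and -0.25 at P5, and -0.00, -0.04 and -0.06 after each library was scaled to the same upper quartile. A gene is therefore said to have risen or fallen where it passed adjusted p 0.05 in the same direction before and after that scaling, and "scaled" marks the fold change after it. This rule, and the genes named outside the rule given with the methods, were chosen after the values were seen. Libraries of a group correlated at 0.987 to 0.997 and libraries of different genotype at 0.967 to 0.980 within a stage (Pearson, across genes of log2 values). The first principal component carried 74.4%, 73.9% and 81.9% of the variance at E17, P0 and P5, and the wild-type and double knockout libraries lay apart on it at each stage.

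The targeted genes were read first. Hmgn2 (chromosome 4, 133964738 to 133968650 of the mm10 build) stood at 354, 344 and 320.0 RPKM in the wild-type libraries at E17 and at 0.839, 0.953 and 0.975 in the double knockout, with a log2 fold change of -7.47 ± 0.07, adjusted p = 3.59e-11, scaled -7.68. At P5 it fell from 183, 166 and 166 to 9.05, 5.44 and 10.4 RPKM (-4.26 ± 0.16, adjusted p = 2.89e-07, scaled -4.04). Hmgn1 (chromosome 16, 96120618 to 96127729) was lowered less. It stood at 133, 129 and 123 RPKM against 86.2, 92.9 and 92.7 at E17 (-0.50 ± 0.07, adjusted p = 0.00137, scaled -0.79). At P5 it stood at 187, 189.6 and 179 against 72.6, 69.8 and 72.2 (-1.36 ± 0.05, adjusted p = 2.89e-07, scaled -1.14). Every double knockout library was below every wild-type library for both genes at both stages. The labels do not describe the alleles, and the gene sums do not separate reads of the targeted exons from reads of remaining exons or of processed copies elsewhere in the genome. Dhdds, which encodes a subunit of the enzyme of dolichol synthesis and lies beside Hmgn2 (chromosome 4, 133969028 to 134000918), fell at E17 (-0.56, scaled -0.82) and at P5 (-1.34, scaled -1.14).

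**Figure D1:**
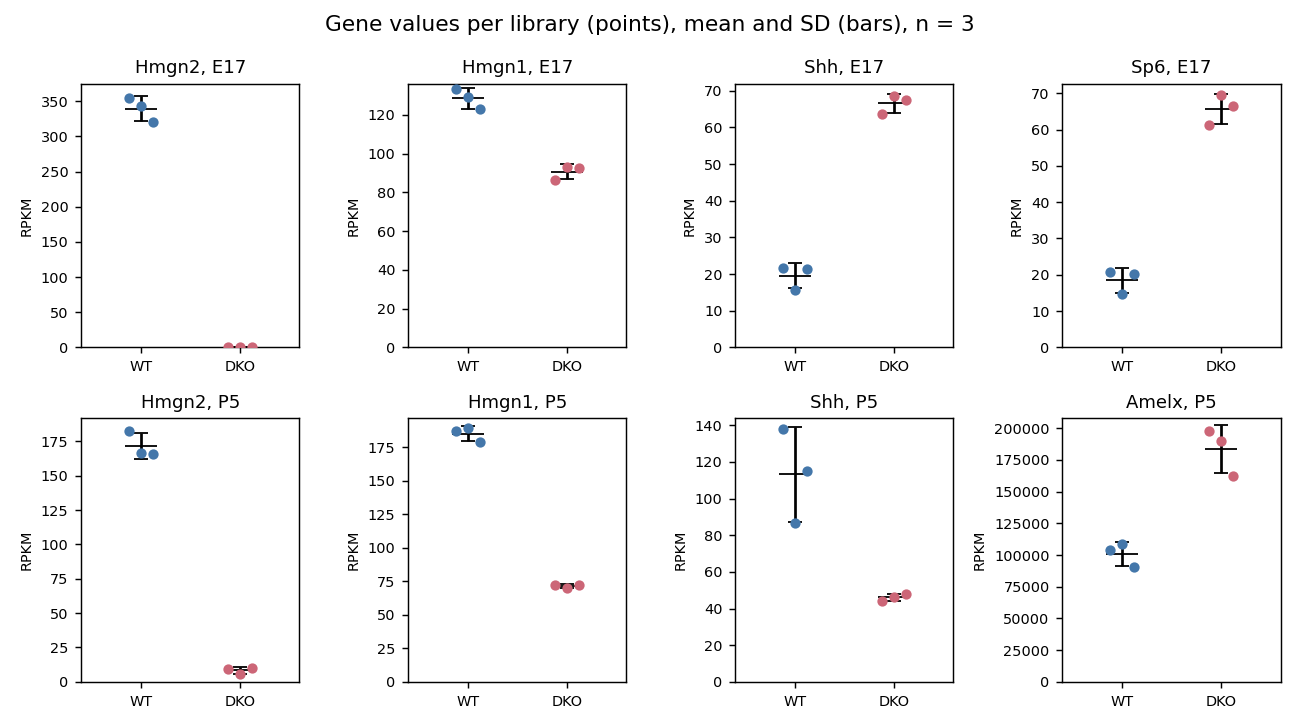
RPKM per library (points) with the mean and SD of each group of 3 for Hmgn2, Hmgn1, Shh and Sp6 at E17 (top) and Hmgn2, Hmgn1, Shh and Amelx at P5 (bottom). Shh lay above wild type in the double knockout at E17 (66.6 ± 2.62 against 19.6 ± 3.39 RPKM) and below it at P5 (46.1 ± 1.75 against 113 ± 25.9 RPKM).

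At E17, the list of signals of the inner enamel epithelium lay above other genes in the double knockout, and the odontoblast and osteoblast, mesenchyme and muscle lists lay below them. With an estimated correlation none of these passed in camera (adjusted p = 0.199, 0.199, 0.478 and 0.199, and after scaling 0.257, 0.257, 0.501 and 0.501). Shh, the Hedgehog ligand secreted by the inner enamel epithelium (chromosome 5, 28456815 to 28467256), rose from 19.6 ± 3.39 to 66.6 ± 2.62 RPKM (1.73 ± 0.11, adjusted p = 7.22e-05, scaled 1.45). Sp6 (epiprofin), a zinc-finger factor needed for ameloblast differentiation, rose from 18.4 ± 3.36 to 65.7 ± 4.17 RPKM (1.79 ± 0.12, adjusted p = 7.84e-05, scaled 1.51). Msx2, a homeobox factor of tooth epithelium, rose from 6.38 ± 0.291 to 23.1 ± 2.01 RPKM (1.70 ± 0.08, adjusted p = 8.96e-06, scaled 1.44). Nts, which encodes the secreted peptide neurotensin, rose from 2.74 ± 0.0341 to 52.2 ± 5.15 RPKM (3.82 ± 0.08, adjusted p = 2.17e-08, scaled 3.57). Col1a1, the main collagen chain of bone and dentin, fell from 1975 ± 135 to 896 ± 119 RPKM (-1.15 ± 0.12, adjusted p = 0.000452, scaled -1.44). Of 13728 genes tested, 1330 changed in both scalings, 908 upward and 422 downward. Before scaling 8188 genes passed, 7735 higher and 453 lower (94.5% higher), and after it 2011, 908 higher and 1103 lower (45.2% higher).

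The list of signals of the inner enamel epithelium and enamel knot, the signalling centre of the tooth germ, rose at E17: 10 of 19 members rose and 0 fell (16 and 0 before scaling). The camera adjusted p was 0.00522 before and 1.69e-05 after scaling, a call that was lost at adjusted p = 0.199 with an estimated correlation. Beside Shh, the growth factors Bmp7 (0.87, scaled 0.61), Wnt6 (0.99, scaled 0.72), Wnt10a (0.73, scaled 0.47) and Fgf9 (0.91, scaled 0.70) rose. Among 34 dental epithelial transcription factors, 14 rose and 3 fell (22 and 3 before scaling). Dlx2 (1.24, scaled 0.96), Foxi3 (1.10, scaled 0.83) and the chromatin organiser Satb1 (0.74, scaled 0.50) were among those that rose. Sox2 (-0.46, scaled -0.73), Nkx2-3 (-0.51, scaled -0.78) and Dlx6 (-0.40, scaled -0.66) fell. The transcription factor list had a camera adjusted p of 0.409 before scaling and 0.00160 after it, the latter lost at adjusted p = 0.501 with an estimated correlation. Of 18 progenitor markers, 5 rose, among them the Wnt inhibitor Sfrp5 (1.09, scaled 0.87) and the Hedgehog receptor Ptch1 (0.75, scaled 0.47). The stem cell genes Lgr5 (-0.34, scaled -0.58), Lrig1 (-0.33, scaled -0.59) and Sox2 fell (adjusted p = 0.927 for the list). Adjusted over the list alone, 16 signals, 26 transcription factors and 16 progenitor markers passed before scaling.

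Enamel matrix genes were near the floor at E17. Amelx (amelogenin, the main enamel protein) went from 5.06 ± 0.558 to 5.18 ± 1.40 RPKM (0.01 ± 0.15, adjusted p = 0.959, scaled -0.23) and did not pass. Enam, Mmp20, Klk4, Amtn and Dspp were below the filter, and 6 of the list's genes were tested. Odam, which encodes an ameloblast protein secreted from the maturation stage on, rose from 1.62 ± 0.593 to 8.60 ± 1.01 RPKM (1.89 ± 0.16, adjusted p = 0.000187, scaled 1.67). Ambn (ameloblastin) had a log2 fold change of -0.35 ± 0.13, adjusted p = 0.0487, scaled -0.59. That call was lost without wild-type replicate 2 (adjusted p = 0.147) or 3 (0.0873), without double knockout replicate 1 (0.128) or 3 (0.0895), and without the trend in limma (0.0522). Of 19 ion transport and maturation genes, 3 rose, the gap junction gene Gja1 (0.96, scaled 0.67), Car12 (0.51, scaled 0.25) and Ctsk (0.78, scaled 0.49). The citrate transporter Slc13a5 fell from 9.80 to 3.38 RPKM (-1.32, scaled -1.57). In the list of the stratum intermedium and stellate reticulum, the layers above the ameloblasts, Vwde (1.46, scaled 1.21), Gjb6 (0.74, scaled 0.53), Enpp2 (0.71, scaled 0.43) and Krt17 (0.61, scaled 0.32) rose of 18 tested. Ibsp, better known as a bone matrix protein, fell (-1.22, scaled -1.51). Alpl, the phosphatase of this list, stood at -0.07 ± 0.12, adjusted p = 0.624, scaled -0.36 and the basal keratin Krt14 at 0.14 ± 0.09, adjusted p = 0.176, scaled -0.15, neither past the threshold, although Krt14 passed without wild-type replicate 1 (0.0449). Of 33 basal keratin and junction genes 10 rose, including Cldn1 (0.90, scaled 0.63) and the desmosomal Dsc3 (0.77, scaled 0.49). Krt15 fell (-0.42, scaled -0.71; not past without wild-type replicate 1 or 3, adjusted p = 0.0982 and 0.0799, or double knockout replicate 2, 0.109). The camera adjusted p was 0.116 for enamel matrix, 0.902 for ion transport, 0.890 for the stratum intermedium and 0.474 for keratins and junctions. Adjusted over the list alone, 1, 12, 11 and 22 members of these lists passed before scaling.

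Markers of other tissues moved with genotype at E17. Of 22 genes of cornifying oral epithelium and skin 10 rose and 0 fell (17 and 0 before scaling; camera adjusted p = 0.0170, scaled 1.10e-06, adjusted p = 0.960 with an estimated correlation). They include Lor (loricrin, the main protein of the cornified envelope, 3.23, scaled 2.96), Krt16 (1.44, scaled 1.16) and Krt6b (2.02, scaled 1.75). Among the genes with the largest increases were the cornified envelope genes Lce3f (4.55, scaled 4.39), Lce3e (3.70, scaled 3.53), Rptn (2.79, scaled 2.63) and Crct1 (3.66, scaled 3.40), with Slpi (3.22, scaled 3.02) and Nccrp1 (2.78, scaled 2.62). Lce3a was listed at 0 in every wild-type library and at 31.7, 5.44 and 27.6 RPKM in the double knockout, and Psca (2.66, scaled 2.39) did not pass after scaling (adjusted p = 0.0569). Replicate 2 of the double knockout stood below the other 2: without it the log2 fold changes were 5.45 for Lce3f, 4.52 for Lce3e, 4.37 for Crct1, 3.80 for Lor and 3.45 for both Nccrp1 and Psca. The summed RPKM of the cornifying list was 3401, 2354 and 3006 in wild type and 5865, 2867 and 5346 in the double knockout replicates 1, 2 and 3. Skeletal muscle genes fell, 12 of 20 with 0 rising (camera adjusted p = 3.02e-29, scaled 1.74e-09, adjusted p = 0.199 with an estimated correlation). Embryonic myosin Myh3 (-1.72, scaled -2.00) and the myogenic factor Myod1 (-1.22, scaled -1.42) were among them, and the list sums were 2252, 945 and 1809 against 927, 1041 and 1065. Odontoblast and osteoblast genes fell, 7 of 17 (adjusted p = 5.05e-17, scaled 4.99e-08, adjusted p = 0.199 with an estimated correlation). The mineralisation genes Dmp1 (-1.09, scaled -1.35) and Phex (-0.76, scaled -0.97) were among them. Of 24 mesenchyme genes 7 fell, such as Col1a2 (-0.94, scaled -1.23) and Postn (-0.43, scaled -0.72). The mesenchymal factor Twist2 rose (0.80, scaled 0.53; list adjusted p = 5.94e-10, scaled 3.40e-06, adjusted p = 0.478 with an estimated correlation). Col11a2, a cartilage collagen, fell from 55.0 to 14.7 RPKM (-1.88, scaled -2.16). Among members adjusted over the list alone, 17 cornifying, 12 muscle, 7 odontoblast and 7 mesenchyme genes passed before scaling.

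Red cell genes rose at E17 in 6 of 9 cases, for example Alas2, the first enzyme of haem synthesis (1.25, scaled 0.97), and Hba-a1 (1.36, scaled 1.07), and the embryonic globin Hbb-y fell (-1.25, scaled -1.43). The list had an adjusted p of 0.615 before and 0.00222 after scaling, the latter lost at adjusted p = 0.501 with an estimated correlation. Its sums were 6416, 7249 and 5787 in wild type and 10435, 21327 and 13562 in the double knockout. The adult globin pairs Hba-a1 and Hba-a2, and Hbb-bs and Hbb-bt, are near-identical copies whose reads may be shared. None of the 16 endothelial genes passed in limma before scaling (1 at an unadjusted p under 0.05) and 4 passed downward after it. Camera placed the list below other genes (adjusted p = 0.00228, scaled 0.000130, adjusted p = 0.914 with an estimated correlation). Immune genes passed upward in 11 of 22 cases before scaling, 3 passed downward after it and 0 passed in both scalings (adjusted p = 0.815). Among 11 glial and neuronal genes Tubb3 (1.61, scaled 1.35) and Stmn2 (1.65, scaled 1.45), which encode microtubule proteins of neurons, rose (adjusted p = 0.631). Of the salivary gland list only Prom1 was tested and it passed before scaling alone (0.48, scaled 0.24). Adjusted over the list alone, 9 red cell, 0 endothelial, 11 immune, 4 glial and neuronal and 1 salivary genes passed before scaling.

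Cell cycle genes stood higher at E17. Before scaling 33 of 35 passed upward and 0 downward, and 8 rose in both scalings, for example Tyms (0.51, scaled 0.23), Ccnb1 (0.48, scaled 0.20) and Cdk1 (0.51, scaled 0.22). The camera adjusted p was 0.000122, scaled 3.00e-05, adjusted p = 0.914 with an estimated correlation. Among 15 HMG protein and linker histone genes, H1f0 (0.61, scaled 0.32), H1f10 (0.61, scaled 0.32), Hmga1 (0.73, scaled 0.44), Hmgb2 (0.54, scaled 0.25) and Hmgb3 (0.54, scaled 0.26) rose. H1f1 (-1.03, scaled -1.21), H1f4 (-0.71, scaled -0.87) and H1f5 (-0.96, scaled -1.14) fell with Hmgn1 and Hmgn2 (list adjusted p = 0.101). Of 36 histone-modifying enzymes 2 rose, Cbx2 of a Polycomb complex (0.56, scaled 0.30) among them (adjusted p = 0.735). None of 3 Hox genes tested passed in limma (0 at an unadjusted p under 0.05 before and 1 after scaling). Hedgehog pathway genes Ptch1, Hhip (0.81, scaled 0.59) and Foxf2 (1.02, scaled 0.76) rose beside Shh. The co-receptors Cdon (-0.31, scaled -0.56) and Gas1 (-0.24, scaled -0.53) fell (15 tested, adjusted p = 0.869). Of 25 Wnt pathway genes 7 rose, with Notum (1.07, scaled 0.81) and Tcf7 (0.93, scaled 0.66) among them, and Lgr5 fell (adjusted p = 0.623). Of 27 BMP and TGF-beta genes 7 rose and 0 fell, Id4 (1.36, scaled 1.09) and Bambi (0.78, scaled 0.51) among the former (adjusted p = 0.136). In the FGF list of 21, Etv4 (1.09, scaled 0.81), Etv5 (0.50, scaled 0.24), Dusp6 (0.72, scaled 0.44), Fgf3 (1.08, scaled 0.85) and Fgf9 rose. Fgfr4 (-0.97, scaled -1.14), Fgf18 (-0.51, scaled -0.73) and Fgf2 (-0.24, scaled -0.45) fell (adjusted p = 0.674). Calls lost with a library left out were Cdon (adjusted p = 0.0535 without wild-type replicate 3) and Fgf18 (0.0756 and 0.0559 without wild-type replicates 1 and 3, 0.05004 without double knockout replicate 2). Fgf2 did not pass with any library but wild-type replicate 2 left out (0.113 and 0.0809 without wild-type replicates 1 and 3, and 0.0790, 0.0758 and 0.0503 without double knockout replicates 1, 2 and 3). With p adjusted over the list alone, 33 cell cycle, 15 HMG, 19 enzyme, 0 Hox, 10 Hedgehog, 16 Wnt, 17 BMP and 17 FGF genes passed before scaling.

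Abundant non-coding RNA was lower in the double knockout at E17, 6 of 12 genes falling and 0 rising (camera adjusted p = 7.11e-18, scaled 4.08e-06, adjusted p = 0.199 with an estimated correlation). Rn7s2, a copy of the signal recognition particle RNA (-2.09, scaled -2.38), Rny1 (-1.80, scaled -1.98), Malat1 (-1.11, scaled -1.39) and the mitochondrial 12S ribosomal RNA mt-Rnr1 (-0.58, scaled -0.87) fell. So did Lars2 (-2.04, scaled -2.33), a list member that encodes an enzyme, mitochondrial leucyl-tRNA synthetase. Whether the reads of Lars2 came from its coding exons was not tested. Rn7s1 (-2.01, scaled -2.30) and Rmrp (-2.08, scaled -2.36) did not pass after scaling (adjusted p = 0.0528 and 0.0611), and Rmrp did not pass without wild-type replicate 3 (0.0517) or double knockout replicate 3 (0.0605), nor Rn7s1 without the latter (0.0532). Replicate 1 of the double knockout stood apart: without it the log2 fold changes were -2.92 for Rn7s2, -2.86 for Rn7s1, -2.997 for Rmrp and -2.80 for Lars2, and that of Rmrp was -1.48 without replicate 2. The 5S ribosomal RNA copies n-R5s106, n-R5s118 and n-R5s130 had identical values (-1.77, scaled -1.93). The sums of this list were 8359, 7856 and 7815 RPKM in wild type and 6326, 3195 and 3839 in the double knockout. Of 19 replication-dependent histone genes, whose transcripts mostly lack a poly(A) tail and belong to families of near-identical copies, 7 fell, among them H3c6 (-0.86, scaled -1.02). H4c9 rose (0.64, scaled 0.37; adjusted p = 2.42e-17, scaled 4.18e-05, adjusted p = 0.226 with an estimated correlation). No mitochondrially encoded gene of 13 passed in limma before scaling (0 at an unadjusted p under 0.05) and 3 passed downward after it. The list lay below other genes in camera (adjusted p = 0.00522, scaled 0.000366, adjusted p = 0.960 with an estimated correlation). Immediate-early and heat-shock genes rose in 5 of 23 cases, Ier3 (0.90, scaled 0.64), Junb (0.71, scaled 0.43), Ier2 (0.64, scaled 0.36), Ier5 (0.74, scaled 0.46) and Btg2 (0.51, scaled 0.25) (adjusted p = 0.400). Unfolded protein response genes rose in 0 of 21 cases in both scalings, against 16 upward before scaling (adjusted p = 0.623). Among neighbours of Hmgn1 on chromosome 16 Pcp4 rose (0.84, scaled 0.57) of 18 tested (adjusted p = 0.623). Among 28 neighbours of Hmgn2 on chromosome 4 Trnp1 (0.76, scaled 0.53), Kdf1 (0.52, scaled 0.26), Cnksr1 (0.50, scaled 0.28) and Stmn1 (0.57, scaled 0.28) rose and Dhdds fell (adjusted p = 0.623). The X-inactivation RNA Xist stood at 52.6, 53.6 and 62.1 RPKM in wild type and 37.9, 13.3 and 34.7 in the double knockout (-1.07, scaled -1.35, not past without wild-type replicate 3, 0.0585). The Y-linked Eif2s3y stood at 5.97, 9.11 and 5.87 against 9.51, 15.9 and 12.6 (0.78, scaled 0.51), in a list of 5 with adjusted p = 0.890. Every library at E17 held both transcripts, so the genotypes may differ in their share of each sex, and a difference of sex was not separated from genotype there. When adjusted over the list alone, 11 non-coding, 13 histone, 0 mitochondrial, 15 immediate-early, 18 unfolded protein response, 9 and 22 neighbour and 5 sex-linked genes passed before scaling.

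Single libraries carried much of the count at E17. Without double knockout replicate 3 the genes past the threshold were 5352 before scaling, 661 after it and 529 in both. Without wild-type replicate 3 those after scaling were 773 and those in both 595. After scaling 1245 passed without double knockout replicate 2 and 1330 without double knockout replicate 1. Camera compares a list with the other genes. At E17 its direction was down while the median before scaling was above 0 for endothelium (0.04), mitochondrial genes (0.04), enamel matrix (0.04), HMG genes (0.44, mean -0.38), immune (0.23), Hedgehog (0.32), FGF (0.38), sex-linked genes (0.78) and neighbours of Hmgn1 (0.21). The direction was up after scaling for the HMG, Hedgehog, FGF and sex-linked lists and down for enzymes (-0.04) and the unfolded protein response (-0.03). After scaling the mean had the other sign than the median for enamel matrix (0.03 and -0.20), ion transport (-0.02 and 0.01) and HMG genes (-0.64 and 0.16).

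At P0, within the chromosomes covered, the ion transport and unfolded protein response lists lay above other genes in the double knockout and the cell cycle list below them. None passed with an estimated correlation (adjusted p = 0.0536, 0.198 and 0.198, and after scaling 0.0852, 0.105 and 0.165). Nts rose from 2.996 ± 0.548 to 76.2 ± 2.01 RPKM (4.28 ± 0.10, adjusted p = 6.25e-11, scaled 4.30). Col1a1 rose from 511 ± 41.5 to 2263 ± 488 RPKM (2.12 ± 0.14, adjusted p = 3.78e-07, scaled 2.15). Slc13a5, a plasma membrane transporter of citrate, rose from 1.25 ± 0.357 to 8.29 ± 0.268 RPKM (2.06 ± 0.12, adjusted p = 1.76e-07, scaled 2.08). Edar, the ectodysplasin receptor of tooth and hair placodes, fell from 3.07 ± 0.561 to 0.620 ± 0.0758 RPKM (-1.32 ± 0.12, adjusted p = 5.04e-06, scaled -1.31). Of 2062 genes tested 815 changed in both scalings, 345 upward and 470 downward. Before scaling 823 passed (345 higher, 478 lower) and after it 976 (444 higher, 532 lower).

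The genes with the largest increases at P0, after Nts, were Stac3, an adaptor of excitation-contraction coupling (3.10, scaled 3.12), Ildr2 (2.55, scaled 2.56), Col1a1, Slc13a5 and the cobalamin carrier Tcn2 (1.86, scaled 1.88). They were followed by Tspan8 (1.78, scaled 1.80), Coro6 (1.78, scaled 1.79), Slc41a2 (1.63, scaled 1.65) and Serpinf1 (1.59, scaled 1.61). Those with the largest decreases were the growth factor target Ccn2 (-1.42, scaled -1.40), Lypd1 (-1.39, scaled -1.38), Mfap4 (-1.38, scaled -1.36), Col13a1 (-1.35, scaled -1.34) and, after these, the potassium channel subunit Kcnmb4 (-1.35, scaled -1.33) and Edar. They were followed by the globin Hba-a2 (-1.31, scaled -1.29), the neurotrophin receptor Ngfr (-1.29, scaled -1.27) and Twist2 (-1.29, scaled -1.27). Kcnmb4os2 fell as well (-1.43, scaled -1.42), and it overlaps Kcnmb4 on the other strand, so without stated strand its reads cannot be told from those of Kcnmb4.

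All 5 ion transport and maturation genes tested at P0 rose. They were Slc13a5, the calcium pump Atp2b1 (1.35, scaled 1.37), Lamb3 (0.83, scaled 0.85), the magnesium transporter Cnnm4 (0.65, scaled 0.67) and Gja1 (0.33, scaled 0.36; not past without wild-type replicate 2, 0.0590, or double knockout replicate 1, 0.0799). The camera adjusted p was 5.08e-05, scaled 0.000295, and adjusted p = 0.0536 with an estimated correlation. Wnt10a rose from 16.2 to 45.4 RPKM (1.44, scaled 1.46) and Wnt6 from 65.1 to 137 RPKM (1.07, scaled 1.09), so that 2 of the 3 inner enamel epithelium signals tested rose and Edar fell. Of 3 transcription factors Dlx3 (0.41, scaled 0.44) and Dlx4 (0.69, scaled 0.71), homeobox genes of which Dlx3 is needed for normal enamel, rose and Tfap2b fell (-0.82, scaled -0.81). Of 4 keratin and junction genes 3 rose, among them the laminin chain Lamb3, which binds the epithelium to its basement membrane, and Perp (0.58, scaled 0.60). Of 5 unfolded protein response genes 3 rose, the secretory pathway regulator Xbp1 (0.92, scaled 0.94), Hsp90b1 (0.46, scaled 0.48) and Atf6 (0.49, scaled 0.50). The list had adjusted p = 0.00279, scaled 0.00419, and adjusted p = 0.198 with an estimated correlation. All 5 cell cycle genes fell, Cdk1 (-0.91, scaled -0.89), Aurkb (-0.93, scaled -0.90), Mcm6 (-0.75, scaled -0.73), Mcm3 (-0.74, scaled -0.72) and Cenpf (-0.61, scaled -0.59; adjusted p = 0.000146, scaled 0.000295, adjusted p = 0.198 with an estimated correlation). Adjusted over the list alone, 5 ion transport, 3 signal, 3 transcription factor, 3 keratin and junction, 4 unfolded protein response and 5 cell cycle genes passed before scaling.

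Mesenchyme genes moved both ways at P0. Of 10 tested, Col1a1 and the proteoglycan Dcn (1.59, scaled 1.61) rose, and 6 fell, among them Twist2, Mfap4 and Col3a1 (-1.09, scaled -1.07; adjusted p = 0.313). The sums of this list were 935, 788 and 946 RPKM in wild type and 2220.2, 3056 and 2798 in the double knockout. Col1a1 alone made up most of them, at 533, 463 and 536 RPKM in wild type and 1727, 2682 and 2379 in the double knockout. Of 3 odontoblast and osteoblast genes 3 rose, Rgs4 (0.40, scaled 0.41) and Col1a1 among them. The endothelial factor Sox17 fell (-0.62, scaled -0.61) as the single member tested. The immune genes Fcer1g (-0.43, scaled -0.41) and Cd68 (-0.40, scaled -0.38) fell of 3, and Erbb3 fell of 3 glial genes (-0.39, scaled -0.38). Hba-a2 fell while its near-identical copy Hba-a1 stood at -0.04, scaled -0.02, so the pair is uncertain (2 red cell genes tested). None of 3 muscle genes passed in limma (0 at an unadjusted p under 0.05 before and 0 after scaling). Gli1, a target of Hedgehog signalling, rose (0.23, scaled 0.25) and Disp1, which releases the ligand, fell (-0.31, scaled -0.30) of 3 Hedgehog genes. Lgr6 fell (-0.28, scaled -0.26) of 3 progenitor markers that also hold Gli1. Wif1 rose (0.81, scaled 0.83) and Tcf7 fell (-0.76, scaled -0.74) of 4 Wnt genes. Tgfb2 rose (0.71, scaled 0.73) and the BMP antagonist Nog fell (-0.78, scaled -0.76) of 3 BMP and TGF-beta genes, and both FGF genes tested fell, Dusp6 (-0.83, scaled -0.81) and Spred2 (-0.54, scaled -0.52). Ier5 (-0.55, scaled -0.53) and Atf3 (-0.48, scaled -0.46) fell of 3 immediate-early genes, and Hmga2 fell (-0.41, scaled -0.39) as the single HMG gene tested. None of 6 histone-modifying enzymes passed in limma before scaling (1 at an unadjusted p under 0.05), against 2 upward and 1 downward after it (list adjusted p = 0.775, median 0.04, mean -0.00). In counts adjusted over the list alone, before scaling, 8 mesenchyme, 3 odontoblast, 1 endothelial, 2 immune, 2 glial, 1 red cell, 0 muscle, 2 Hedgehog, 2 progenitor, 2 Wnt, 2 BMP, 2 FGF, 2 immediate-early, 1 HMG and 0 enzyme genes passed. Lists with fewer than 5 genes tested had no camera test, and the other lists had no gene tested at P0. Calls near the threshold were lost with a library left out for Gli1 (0.0544 without wild-type replicate 1, 0.0749 without double knockout replicate 1, 0.103 without 3) and Disp1 (0.0544 and 0.0788 without replicate 1 of wild type and double knockout). The same held for Cd68 (0.0804 and 0.0539 without wild-type replicates 1 and 3, 0.0893 without double knockout replicate 3), Hmga2 (0.0564 without wild-type replicate 1) and Rgs4 (0.0565 without double knockout replicate 3). Lgr6 did not pass with either replicate 1 or 3 left out (0.0666 and 0.146 without wild-type replicates 1 and 3, 0.154 and 0.165 without double knockout replicates 1 and 3).

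At P5, when ameloblasts secrete enamel, the enamel matrix list lay above other genes in the double knockout, and the cell cycle, odontoblast and mesenchyme lists below them. These calls ended with an estimated correlation (adjusted p = 0.240, 0.700, 0.714 and 0.853, and after scaling 0.400, 0.0611, 0.400 and 0.715). Amelx (chromosome X, 169176114 to 169187200) rose from 100892 ± 9306 to 183477 ± 18718 RPKM (0.86 ± 0.11, adjusted p = 8.68e-05, scaled 1.09). Ambn rose from 16097 ± 1727 to 33517 ± 1845 RPKM (1.06 ± 0.09, adjusted p = 1.11e-05, scaled 1.29). Amtn (amelotin, a protein of maturation-stage ameloblasts) rose from 21.1 ± 14.03 to 104 ± 23.4 RPKM (2.44 ± 0.37, adjusted p = 0.000249, scaled 2.65). Nts rose from 6.15 ± 1.78 to 146 ± 54.4 RPKM (4.33 ± 0.23, adjusted p = 2.12e-06, scaled 4.54). Shh fell from 113 ± 25.9 to 46.1 ± 1.75 RPKM (-1.25 ± 0.13, adjusted p = 3.19e-05, scaled -1.03). Of 11423 genes tested 4355 changed in both scalings, 840 upward and 3515 downward. Before scaling 7486 passed, 841 higher and 6645 lower (11.2% higher), and after it 5726, 2211 higher and 3515 lower (38.6% higher).

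The enamel matrix and protease list rose at P5, 9 of 13 members rising (camera adjusted p = 3.34e-11, scaled 7.97e-06, adjusted p = 0.240 with an estimated correlation). Enam (enamelin, 0.67, scaled 0.89), the enamel protease Mmp20 (0.59, scaled 0.82), the phosphatase Acp4 (0.79, scaled 1.01) and the secretory pathway kinase Fam20c (0.38, scaled 0.61) were among them. Dspp, a dentin gene that early ameloblasts also express, fell from 408 to 180.0 RPKM (-1.15, scaled -0.93). The late protease Klk4 passed only after scaling or without wild-type replicate 3 (0.23, scaled 0.42, adjusted p = 0.131, 0.0357 and 0.00878), and Odam did not pass (-0.12, scaled 0.11, adjusted p = 0.217). Ion transport and maturation genes moved both ways. Of 21 tested 8 rose, including the receptor Relt (0.57, scaled 0.79), Lamb3 (0.60, scaled 0.82) and Slc13a5 (0.40, scaled 0.62). Car2 (-1.14, scaled -0.93), Cnnm4 (-0.80, scaled -0.60), Tfrc (-0.40, scaled -0.20) and Slc26a6 (-0.44, scaled -0.27) fell (adjusted p = 0.00302, scaled 0.0507, adjusted p = 0.812 with an estimated correlation). Of 30 keratin and junction genes 8 rose, for example Cldn1 (0.65, scaled 0.87). Dsc2 (-0.51, scaled -0.31), Jup (-0.42, scaled -0.21) and Epcam (-0.50, scaled -0.28) fell (adjusted p = 0.000567, scaled 0.00206, adjusted p = 0.832 with an estimated correlation). Csn3, which encodes kappa-casein, a secreted relative of the enamel matrix genes, rose from 43.4 ± 18.7 to 283 ± 175 RPKM (2.57, scaled 2.79). Before scaling, 10 enamel matrix, 18 ion transport and 16 keratin and junction genes passed when adjusted over the list alone.

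Among 14 inner enamel epithelium signals at P5, Bmp4 (0.56, scaled 0.79), Bmp7 (0.29, scaled 0.51), Edar (0.55, scaled 0.69), Fst (0.42, scaled 0.59) and Cdkn1a (0.25, scaled 0.47) rose. Shh, Bmp2 (-1.27, scaled -1.09) and Sostdc1 (-0.48, scaled -0.25) fell (adjusted p = 0.0283, scaled 0.139, adjusted p = 0.700 with an estimated correlation). Of 30 transcription factors 5 rose and 8 fell (adjusted p = 0.520). Runx1 (0.35, scaled 0.56), Runx2 (0.26, scaled 0.45), Sox21 (0.30, scaled 0.52), Rora (0.53, scaled 0.70) and Dlx1 (0.39, scaled 0.59) rose. Sp7 (osterix, -1.34, scaled -1.14), Irx1 (-1.10, scaled -0.88), Msx1 (-0.95, scaled -0.75) and Foxo1 (-0.91, scaled -0.69) were among those that fell. Sp6 (-0.31, scaled -0.09) passed before scaling (adjusted p = 0.0103) and not after it (0.359), and Satb1 (-0.15, scaled 0.07) passed only without wild-type replicate 2 (0.0127). The bHLH factor Ascl5 fell from 17.996 to 2.57 RPKM (-2.41, scaled -2.22). It was among the largest decreases, with the Wnt activator Rspo4 (-2.42, scaled -2.22), the Wnt inhibitor Dkk1 (-1.77, scaled -1.62), Crabp1 (-1.91, scaled -1.71), Cpne1 (-1.66, scaled -1.46) and the histone H2ac24 (-1.66, scaled -1.46). The largest increases, beside Nts, Csn3 and Amtn, were the cell cycle inhibitor Cdkn2b (1.56, scaled 1.74), the potassium channel Kcna3 (1.40, scaled 1.603) and Arrdc4 (1.37, scaled 1.59). They were followed by Il17rd, an inhibitor of FGF signalling (1.36, scaled 1.54), Slc16a6 (1.22, scaled 1.41) and Rasgef1b (1.21, scaled 1.42). Of 13 progenitor markers Ptch1 and Lgr6 (1.06, scaled 1.22) rose and Pcp4 fell (-1.38, scaled -1.19; adjusted p = 0.128). In the stratum intermedium list of 19 the Notch ligands Jag1 (0.41, scaled 0.63) and Jag2 (0.18, scaled 0.40) rose. The Notch targets Hey1 (-1.15, scaled -0.93) and Heyl (-0.64, scaled -0.46), Fgf13 (-0.75, scaled -0.63) and the bone gene Ibsp (-0.92, scaled -0.70) fell (adjusted p = 0.795). Alpl (-0.38, scaled -0.15) passed only before scaling (adjusted p = 0.00126 and 0.0581) and Krt14 did not pass (-0.09, scaled 0.13, adjusted p = 0.231). Calls lost with a library left out were Fst (adjusted p = 0.110 and 0.0816 without wild-type replicates 1 and 3, 0.0661 and 0.0521 without double knockout replicates 1 and 3) and Runx2 (0.0570 and 0.0575 without wild-type replicates 1 and 3, 0.0886 without double knockout replicate 1). Nor did Jag2 pass with some of them left out (0.0932 and 0.0625 without wild-type replicates 2 and 3, 0.0846 and 0.0577 without double knockout replicates 2 and 3). Counts adjusted over the list alone before scaling were 10 signals, 17 transcription factors, 4 progenitor and 12 stratum intermedium genes.

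**Figure D2:**
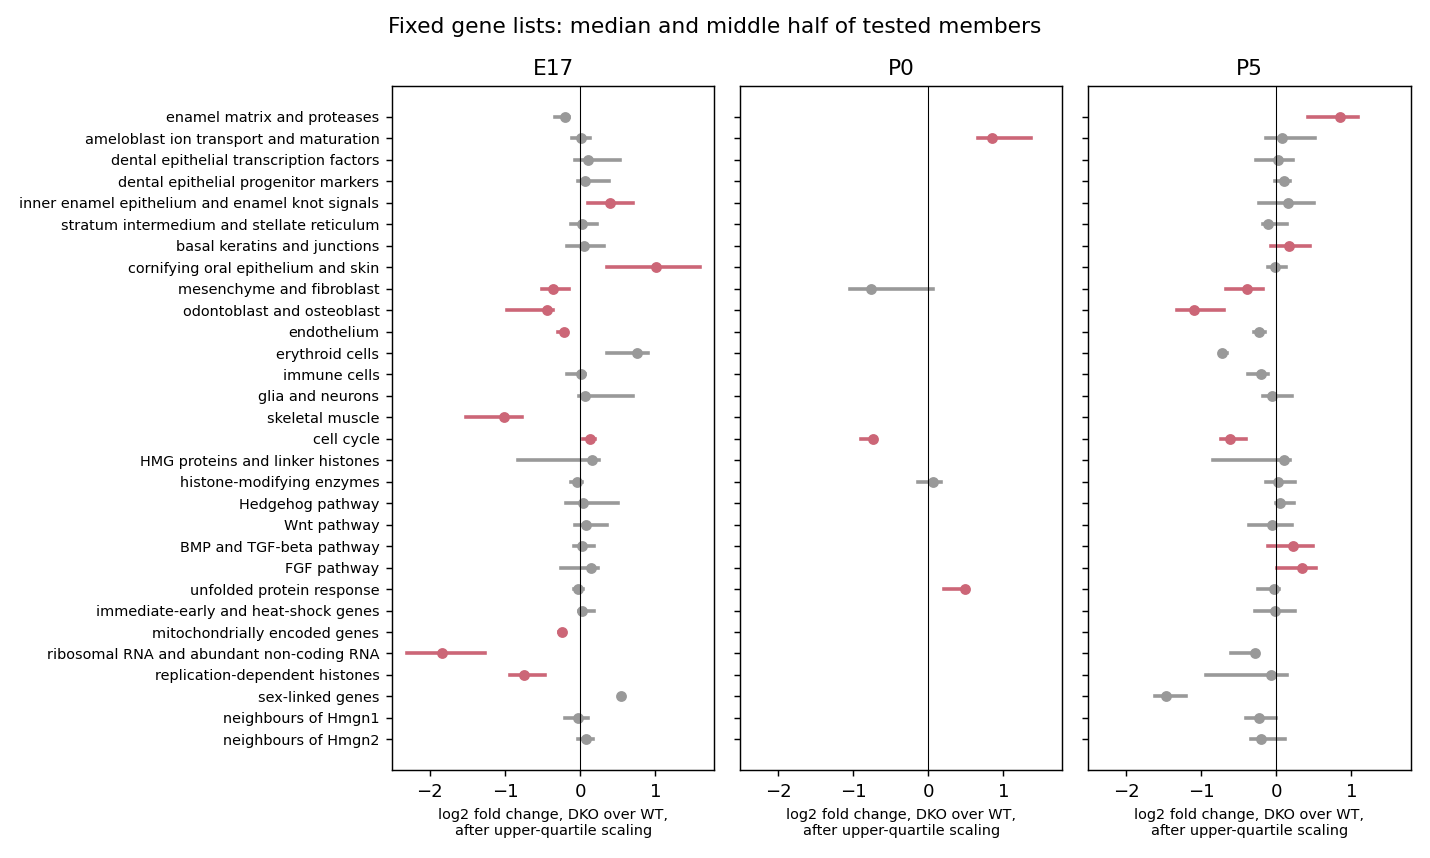
Median (point) and interquartile range of the members tested (bar) of the scaled log2 fold changes of each gene list at E17, P0 and P5, coloured where the list passed adjusted p 0.05 in camera in both scalings. Enamel matrix genes had a scaled median of 0.84 at P5, and cell cycle genes had 0.13 at E17, -0.73 at P0 and -0.61 at P5.

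Cell cycle genes fell at P5, 28 of 32 with 0 rising, for example Mki67 (-1.02, scaled -0.85), Top2a (-0.96, scaled -0.77) and Cdc20 (-1.03, scaled -0.85; adjusted p = 1.16e-05, scaled 2.60e-08, adjusted p = 0.700 with an estimated correlation, scaled 0.0611). Odontoblast and osteoblast genes fell, 14 of 17, such as Dmp1 from 29.2 to 4.05 RPKM (-2.55, scaled -2.35) and the sphingomyelinase Smpd3 (-1.77, scaled -1.59), and Runx2 rose (adjusted p = 0.00344, scaled 0.000442, adjusted p = 0.714 with an estimated correlation). Mesenchyme genes fell in 13 of 22 cases, Col1a1 (-1.18, scaled -0.96), Lum (-1.57, scaled -1.35), Vim (-0.92, scaled -0.70) and Fn1 (-1.13, scaled -0.93) among them (adjusted p = 0.0139, scaled 0.00498, adjusted p = 0.853 with an estimated correlation). The list sums were 2535, 2469.9 and 2319.6 RPKM in wild type and 1480.0, 1387 and 1077 in the double knockout. Red cell genes fell in 7 of 8 (Hbb-bs -0.96, scaled -0.74; list adjusted p = 0.2504; sums 2045, 2086 and 1895 against 976, 737 and 1632), where Hbb-b2 and Hbb-bt had identical values. Endothelial genes Sox18 (-1.09, scaled -0.91), Erg (-0.57, scaled -0.43), Eng (-0.56, scaled -0.36), Tie1 (-0.50, scaled -0.31) and Kdr (-0.47, scaled -0.29) fell of 16 (adjusted p = 0.210). The macrophage genes Lyz2 (-0.48, scaled -0.27), Csf1r (-0.60, scaled -0.42), Cx3cr1 (-0.49, scaled -0.35), Tyrobp (-0.88, scaled -0.68) and Cd68 (-0.55, scaled -0.38) fell of 16 immune genes (adjusted p = 0.520). Of 6 glial and neuronal genes 1 rose and Tubb3 fell (-1.36, scaled -1.14; adjusted p = 0.527). Elovl4 (-0.46, scaled -0.30) and Lor (-0.36, scaled -0.24) fell of 12 cornifying genes (adjusted p = 0.527), and the single muscle gene tested, Mylpf, did not pass (0.79, scaled 0.93, adjusted p = 0.150). It passed without double knockout replicate 2 (0.0412), and without replicate 3 its log2 fold change was 0.08. Adjusted over the list alone, 30 cell cycle, 16 odontoblast, 18 mesenchyme, 8 red cell, 14 endothelial, 13 immune, 2 glial and neuronal, 4 cornifying and 0 muscle genes passed at P5 before scaling. No salivary, Hox or mitochondrially encoded gene was tested at P5.

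The linker histones H1f2, which rose from 48.3 ± 1.46 to 102 ± 5.67 RPKM (1.05, scaled 1.28), and H1f0 (0.64, scaled 0.87) were higher at P5. Hmgn3 (-1.06, scaled -0.84), H1f3 (-1.25, scaled -1.11) and H1f4 (-0.98, scaled -0.84) fell with Hmgn1 and Hmgn2 (14 tested, adjusted p = 0.579). Of 34 histone-modifying enzymes 7 rose, among them the demethylase Kdm6a (0.58, scaled 0.77) and Tet2 (0.48, scaled 0.65). Of the same list 7 fell, among them the Polycomb methyltransferase Ezh2 (-1.30, scaled -1.11) and the deacetylases Hdac1 (-0.56, scaled -0.34) and Hdac2 (-0.68, scaled -0.46; adjusted p = 0.303). Of 26 BMP and TGF-beta genes 11 rose, for example Tgfbr1 (0.69, scaled 0.90), and 6 fell, for example Id3 (-1.03, scaled -0.80; adjusted p = 0.000697, scaled 0.00498, adjusted p = 0.714 with an estimated correlation). The FGF targets Etv5 (1.06, scaled 1.25), Etv4 (0.42, scaled 0.59), Spry1 (0.58, scaled 0.76) and Spry2 (0.29, scaled 0.48) rose and Fgfr3 fell (-0.88, scaled -0.72) of 11 FGF genes (adjusted p = 0.000895, scaled 0.00782, adjusted p = 0.240 with an estimated correlation). In the Hedgehog list of 15 genes 3 rose, Ptch1 (0.43, scaled 0.65) and Gli2 (0.24, scaled 0.44) among them, and Shh fell (adjusted p = 0.0431, scaled 0.0798, adjusted p = 0.832 with an estimated correlation). Of 21 Wnt genes Axin2 (0.57, scaled 0.76) and Znrf3 (0.38, scaled 0.56) rose and 7 fell, Wif1 (-0.84, scaled -0.62) and Notum (-0.69, scaled -0.49) among them (adjusted p = 0.660). Of 20 unfolded protein response genes Xbp1 rose (0.21, scaled 0.43), and Chac1 (-1.27, scaled -1.15), Creld2 (-0.73, scaled -0.51), Herpud1 (-0.63, scaled -0.43), Pdia4 (-0.59, scaled -0.37) and Pdia6 (-0.58, scaled -0.35) fell (adjusted p = 0.579). Of 22 immediate-early and heat-shock genes Atf3 (0.53, scaled 0.69), Ier3 (0.29, scaled 0.49) and Ier5 (0.34, scaled 0.56) rose and 7 fell, Hsph1 (-1.03, scaled -0.84) and Klf2 (-0.98, scaled -0.81) among them (adjusted p = 0.660). Calls lost with a library left out were Gli2 (adjusted p = 0.0580 and 0.0683 without wild-type replicates 2 and 3, 0.0848 without double knockout replicate 1) and Spry2 (0.0575 without wild-type replicate 3, 0.0618 and 0.0582 without double knockout replicates 1 and 3). The counts adjusted over the list alone, before scaling, were 8 HMG, 22 enzyme, 18 BMP, 10 FGF, 7 Hedgehog, 11 Wnt, 15 unfolded protein response and 16 immediate-early genes.

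Neat1 fell (-0.51, scaled -0.30) of 6 abundant non-coding RNAs tested at P5 (adjusted p = 0.619), whose sums were 5371, 8943 and 11250.2 RPKM in wild type and 5025, 5679.5 and 7034 in the double knockout. Of 8 replication-dependent histone genes H2bc4 (0.34, scaled 0.56) and H2ac18 (0.27, scaled 0.49) rose, and H3c14 (-1.56, scaled -1.38), H4c4 (-1.18, scaled -1.07) and H4c9 (-1.06, scaled -0.88) fell (adjusted p = 0.520). Among neighbours of Hmgn1 8 of 14 fell, Pcp4 and Vps26c (-0.92, scaled -0.72) included, and Dyrk1a rose (0.19, scaled 0.39; adjusted p = 0.316). Among neighbours of Hmgn2 12 of 25 fell, Dhdds and Stmn1 (-0.86, scaled -0.64) included, and Gpatch3 rose (0.30, scaled 0.46; adjusted p = 0.520). Dyrk1a did not pass without wild-type replicate 2 or 3 (adjusted p = 0.113 and 0.0571) or double knockout replicate 1, 2 or 3 (0.0629, 0.106 and 0.0567), nor Gpatch3 without double knockout replicate 3 (0.0553). The sex of the animals is not in the labels. Xist stood at 0.422, 0.769 and 1.06 RPKM in wild type and 29.0, 32.6 and 1.06 in double knockout replicates 1, 2 and 3 (2.88, scaled 3.02). Eif2s3y stood at 25.9, 23.8 and 24.01 against 1.56, 1.10 and 21.7 (-2.36, scaled -2.18). By these values double knockout replicates 1 and 2 look female and the other 4 libraries male, so the genotype comparison at P5, X-linked Amelx and Kdm6a included, is partly one of sexes. Without double knockout replicate 1, 2 or 3 the log2 fold change of Xist was 2.26, 2.18 or 4.20, and that of Eif2s3y was -1.75 without replicate 2 and -3.46 without replicate 3. Both calls ended without wild-type replicate 1 (adjusted p = 0.0553 and 0.0525; 5 sex-linked genes tested, list adjusted p = 0.781). By p adjusted over the list alone, 5 non-coding, 6 histone, 12 and 16 neighbour and 5 sex-linked genes passed before scaling. At P5 camera placed lists above other genes while their median before scaling was below 0 for ion transport (-0.15), signals (-0.01), keratins and junctions (-0.05), Hedgehog (-0.13), progenitors (-0.11), transcription factors (-0.18), stratum intermedium (-0.30), cornifying (-0.17), glial (-0.22), HMG (-0.10), enzyme (-0.17), Wnt (-0.23), immediate-early (-0.20), histone (-0.22) and sex-linked (-1.59) genes, and the BMP list had a median of 0.00 and a mean of -0.06. After scaling the direction was down for the histone and sex-linked lists, and the median stayed below 0 for the stratum intermedium (-0.11), Wnt (-0.05), immediate-early (-0.02), cornifying (-0.02) and glial (-0.06) lists. The scaled mean was below 0 for transcription factors (-0.04) and HMG genes (-0.35).

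The genotype effect was then compared between stages, gene by gene, as the difference of the log2 fold changes, each from values normalized within its own stage. Shh changed from an increase at E17 to a decrease at P5, a difference of -2.98 ± 0.17, adjusted p = 7.67e-10, scaled -2.48. Sp6 (-2.11, scaled -1.600), Odam (-2.01, scaled -1.57) and Satb1 (-0.89, scaled -0.43) had lower effects at P5, and Ambn (1.41, scaled 1.88) and Amelx (0.85, scaled 1.32) higher ones. Col1a1 had a higher effect at P0 than at E17 (3.27, scaled 3.58) and a lower one at P5 than at P0 (-3.31, scaled -3.11). Of 11049 genes tested at E17 and P5 the effect differed for 3324 in both scalings, 288 higher and 3036 lower at P5 (8916 before scaling and 4880 after it, the latter 3190 without replicate 3 of both genotypes at E17).

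Among cell cycle genes, the effect on Cdk1 (-1.42, scaled -1.11) and Mcm6 (-1.06, scaled -0.76) was lower at P0 than at E17. That on Ccnb1 (-1.53, scaled -1.08) and Top2a (-1.33, scaled -0.85) was lower at P5 than at E17. Tubb3 (-2.97, scaled -2.49), Msx2 (-1.85, scaled -1.36), Dlx2 (-1.44, scaled -0.95) and Hba-a2 (-2.14, scaled -1.63) had lower effects at P5 than at E17 as well. Between E17 and P0 the effect differed for 635 of 2011 genes in both scalings, 155 higher and 480 lower at P0 (1142 before scaling), among them Slc13a5 (3.39, scaled 3.65), Edar (-1.94, scaled -1.70), Kcnmb4 (-2.26, scaled -1.97) and Twist2 (-2.09, scaled -1.80). Between P0 and P5 it differed for 722 of 1758, 174 higher and 548 lower at P5 (942 before scaling), among them Wnt10a (-1.90, scaled -1.70), Wnt6 (-1.48, scaled -1.28), Dcn (-3.14, scaled -2.94) and Edar (1.87, scaled 1.99). The effect on Nts did not differ detectably between P0 and P5 (0.05 ± 0.25, adjusted p = 0.873, scaled 0.24).

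The overlap of calls depended on scaling. Before scaling 412 genes were called higher at both E17 and P5, fewer than the 472 of independent lists (n1 × n2 / N; Fisher's exact test, two-sided, p = 3.23e-06), and after scaling 203, more than the 140 (p = 4.33e-09). By the same exact test, genes called lower at both were 109 against 103 before scaling (p = 0.352) and 273 against 234 after it (p = 0.00166). By the exact test for E17 and P0 the counts were 166 against 185 higher (p = 0.0181) and 10 against 11.5 lower (p = 0.734) before scaling, and 27 against 29.9 (p = 0.595) and 35 against 35.9 (p = 0.920) after it. By the exact test for P0 and P5 they were 34 against 22.5 higher (p = 0.00777) and 243 against 228 lower (p = 0.0916) before scaling, and 113 against 87.4 (p = 0.00056) and 151 against 137 (p = 0.109) after it.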

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

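The tests of less mesenchyme and muscle, of scaling and of cornifying epithelium at E17, that of mesenchyme at P0, and every test of upper-quartile scaling of the differences between stages were chosen only after the results were seen.

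The genotype effect differed between stages by a test of the difference itself for 1142 genes between E17 and P0, 8916 between E17 and P5 and 942 between P0 and P5 before scaling. Among the genes given at every stage, the effect at P5 minus that at E17 was -2.98 for Shh, -2.11 for Sp6, -2.01 for Odam, -0.89 for Satb1, 1.41 for Ambn and 0.85 for Amelx. For the targeted genes it was -0.86, scaled -0.35 (Hmgn1) and 3.21, scaled 3.64 (Hmgn2). Col1a1 differed by 3.27 between E17 and P0 and by -3.31 between P0 and P5. Stage and table go together, with another annotation at P5, so differences of stage and of processing were not separated. Of 100 drawn splits of both stages, 1, 1 and 2 gave as many differing genes for E17 and P0, E17 and P5, and P0 and P5, the real one included. At 0.05 this excludes only chance in the grouping of the libraries at both stages at once. Chance in the grouping at 1 stage alone is not excluded, since a stage has 10 splits. Equal effects at both stages are not what these splits test. The highest others were 874, 5765 and 1099, of which 874 and 1099 came from the real grouping with the labels of 1 stage swapped (768 and 748 in the rest).

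The shift of all genes is the first pattern weighed: at E17 94.5% of calls were higher and at P5 11.2%. With the 10 most abundant genes of a stage left out and the libraries rescaled, the median log2 fold change went from 0.25 to -0.0057 at E17, where those genes fell from 18.4% to 12.4% of the summed values, and from -0.25 to -0.066 at P5, where they rose from 33.0% to 49.0%. These values are what a changed share of a few abundant transcripts predicts, and 1776 and 5742 genes then passed. The rescaling also removed a difference in the summed values, whatever the 10 genes did. At E17 the sums were 468529, 436898 and 431317 RPKM in wild type and 489814, 515783 and 518245 in the double knockout. The test therefore does not show that the 10 genes account for the whole shift at E17. The most abundant of them there, CT010467.1, stood at 40255.1, 40654.5 and 37860.1 RPKM in wild type and 29974.3, 5283 and 8986.3 in the double knockout. Whether ribosomal RNA left after depletion changed the share of these genes was not tested. The share of reads in the listed transcripts, estimated from the values, also differed with genotype at E17. It was 82.3%, 80.5% and 78.9% in wild type and 86.6%, 89.6% and 90.1% in the double knockout. RPKM do not measure amounts per cell, so a change of total RNA per cell stays open and untested.

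The second pattern is the rise of 38 of the signals and transcription factors of the enamel epithelium at E17, before scaling. Less carried-over mesenchyme and muscle would raise all epithelial genes alike and cannot be told apart from genotype: the scaled median of all 19 signals (0.40) lay above the interquartile range of keratin and junction genes (-0.17 to 0.32) and that of all 34 transcription factors (0.0997) within it, while among genes called higher the medians were 0.45 and 0.49 against 0.05 to 0.49. Scaling is not the whole cause, since 24 of these 38 stayed higher past the threshold after it. More cornifying oral epithelium cannot be told apart from genotype: the double knockout library with the lowest cornifying sum (2867 against 5346 and 5865) had a median log2 ratio of 0.0599 for the pattern genes, and 1 library excludes nothing. The sex of the animals, an earlier or later dissection, a different share of inner enamel epithelium among the epithelial cells and an effect of the genotype on these genes stay open, as untested.

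The third pattern is a move of the double knockout along the course from younger to older wild-type molars, read from genes whose wild-type mean differed by at least 1 log2 unit, beyond the median gene, between the other stages, across tables of different annotation for 2 of the 3. At each stage only genes on the chromosomes covered at P0 were compared, and no gene of the enamel matrix list was among them. Genes higher at the later stage had a scaled median above that of genes lower there by 0.67 at P0 (107 of 167 later genes called higher and 12 lower, 85 of 149 earlier genes lower and 6 higher; camera p = 1.33e-19 and 2.88e-11, and 0.0308 and 0.0526 with an estimated correlation) and by 0.27 at P5 (20 of 58 later genes higher and 11 lower, 27 of 63 earlier genes lower and 3 higher; p = 0.0277 and 0.0155, and 0.434 and 0.367). At E17 the difference was -0.0708, and camera placed later genes down (p = 0.280036, and 0.382 with an estimated correlation) and earlier genes up (p = 0.0313, and 0.244). The course read there ran from wild type at P0 to wild type at P5, so these values cannot show a move from E17 towards P0. They give no sign of a move from P0 towards P5 among the genes covered. In the mesenchyme list at P0 2 called genes rose and 6 fell, which argues against a uniform change of its share as the whole cause. A changed mix of mesenchymal tissues can move members both ways, so the list cannot exclude carried-over tissue. The values at P0 go with a double knockout further along the course, those at P5 mostly through earlier genes (scaled median -0.23, against 0.03 for later ones). The course used for P0 ran from wild type at E17 to wild type at P5. Between these the mean wild-type sum went from 1669 to 5.89 RPKM for the muscle list and from 2920 to 87.7 for the cornifying list. Whether carried-over muscle or cornifying tissue moved genes along this course at P0 was not tested. At P5 14 of 17 odontoblast and 13 of 22 mesenchyme genes fell in both scalings (1 and 0 rose). Less carried-over tissue there may lower earlier genes too, and this was not tested. Small differences in age between the litters, or in sex, may give the same values and stay untested.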

How the results depend on the processing

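Median-of-ratios scaling, libraries left out with the filter of all 6 kept, the combinations with upper-quartile scaling and upper-quartile scaling of the differences and overlaps were tests chosen only after the results were seen. At E17 the genes past the threshold fell from 8188 to 2011 with upper-quartile scaling, 2020 with median-of-ratios scaling, and 1657 with upper-quartile scaling and the replicate block. An absolute log2 fold change of at least 1 left 252, 62 and 197 genes at E17, P0 and P5, since it asks more of each gene. No filter, a pseudocount of 0.1 and limma without trend kept the counts at each stage within 1.5 times. With libraries left out the count at E17 went from 5352 to 9183, after upper-quartile scaling from 661 to 2317, and in both scalings from 529 to 1420. The genes that differ between E17 and P5 were 4880 after upper-quartile scaling and 3190 when replicate 3 at E17 was left out too. Genes higher at both E17 and P0 were 96 without a filter, now above the overlap of independent lists, and 27 after upper-quartile scaling, no longer past the threshold. Those higher at both E17 and P5 were 284 without a filter and 203 after upper-quartile scaling, both then above it. Those lower at both E17 and P5 passed with 273 after upper-quartile scaling and with 76 at an unadjusted p under 0.01, and those lower at both P0 and P5 with 189 without a filter. With an estimated correlation 0 lists passed at E17, 0 at P0 and 0 at P5, in either scaling. Without a filter 17 lists passed in camera at E17, but endothelium (adjusted p = 0.460) and mitochondrial genes (0.339) no longer did. At P5 signals (adjusted p = 0.213), Hedgehog (0.213) and FGF (0.185) no longer passed in camera without it. Fry, which does not compare a list with other genes and so takes up the shift of all genes, called 23 lists at E17 and 18 at P5. Of the lists past the threshold in camera or fry before scaling, it reversed the direction at E17 of endothelium (adjusted p = 0.601), immune cells (0.0223), Hedgehog (0.0120), FGF (0.00216), mitochondrial genes (0.627) and neighbours of Hmgn1 (0.00377), and at P5 of ion transport (0.675), transcription factors (0.0134), signals (0.301), stratum intermedium (0.0148), HMG genes (0.00454), histone enzymes (0.0324), Hedgehog (0.781), Wnt (0.0181), BMP (0.472) and immediate-early genes (0.00383), and lists past it in neither turned as well. With the replicate number as a block 7671, 842 and 7103 genes passed at E17, P0 and P5, 341 named genes kept their call and 4 lost it (Fgf2 at E17, Lgr6 at P0, Dyrk1a and Jag2 at P5), and 61 list results kept and 2 gained one. Deviations from the group mean (log2 values) of libraries of the same number correlated at -0.022, 0.220 and -0.021 at E17, at -0.166, 0.270 and -0.081 at P0 and at -0.222, -0.072 and 0.044 at P5. The deviations of the 3 libraries of a group depend on each other, so these values cannot show whether the numbers pair the samples. Of the named genes with a library left out, 1951 results kept their call, 66 lost it and 8 gained one, and none reversed. With upper-quartile scaling 331 of these kept their call, 12 lost it and 2 gained one, and of the list results 58 kept, 3 lost and 2 gained one. Without the trend 343 genes kept their call and 2 lost it. Where no construction is named, the cause was not tested. Tests that need counts were not run, since the values are RPKM. The test of the wild-type course was set for counts on the same gene names at all 3 stages, and was not run either. In simulated data at E17 6% of genes changed by 0.25 log2 units passed. The simulated genes varied independently and had no shift of all genes, so this share does not carry over to the real data. There 8188 of 13728 genes passed at E17 before scaling, and the median absolute log2 fold change of all genes tested was 0.26.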

Other observations

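The comparison of genes shared by stages in both scalings and the single transcripts below were tests chosen only after the results were seen.

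With 3 libraries against 3 there are 10 splits of a stage, too few for a share under 0.05. The real split gave 8188, 823 and 7486 genes at E17, P0 and P5 against 0 as the highest of the other splits at each stage, so 1 of the 10 was as large, the real one included. For gene lists 5, 3 and 3 of the 10 splits gave as many, with 10, 3 and 10 lists in the real split and 14, 3 and 12 as the highest other. For the overlaps of calls, of 100 drawn splits of both stages 2 and 2 were as large for E17 and P0 (higher and lower), 2 and 1 for E17 and P5, and 2 and 1 for P0 and P5, the real one included. The highest others were 318, 13, 4260, 16, 168 and 26 in that order, each from the real grouping with the labels of 1 stage swapped. The rest gave 0 because a stage split otherwise calls 0 genes, so these splits say nothing of the overlap itself, and chance is not excluded by them.

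Of 11049 genes tested at E17 and P5, 84 rose at both stages in both scalings, among them Nts, Ptch1, Etv4, Etv5, Bmp7, Edar, H1f0 and Cdkn2b, and 77 fell at both, among them Hmgn1, Hmgn2, Dhdds, Col1a1, Col1a2, Dmp1, Phex, Ibsp, Panx3 and H1f4. Of all genes tested at a stage, 908 rose and 422 fell at E17, and 840 rose and 3515 fell at P5. The overlap of independent lists was not computed for this rule, so these counts do not show more sharing than chance. Of 1735 genes tested at all 3 stages Nts rose at each and Tnn, which encodes tenascin-N of periosteum and dentin, fell at each.

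CT010467.1, a transcript without a gene name, was the most abundant at E17, at 40255, 40654 and 37860.1 RPKM in wild type and 29974, 5283 and 8986 in the double knockout. Double knockout replicate 1 lay nearest wild type, as it did for Rn7s2 (677 RPKM against 110 and 127 in the others). The same held for Lars2 (935 against 152 and 246). Whether ribosomal RNA left after depletion differed between these libraries was not tested. The summed muscle genes at P5 were 7.17, 5.40 and 5.10 RPKM in wild type and 6.99, 6.22 and 51.2 in the double knockout, so replicate 3 of the double knockout stood apart.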
